A study of Rattus norvegicus with 9 samples.

How the data were processed

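Messenger RNA of cultured 4T1 cells, a mouse mammary carcinoma line, was sequenced on an Illumina HiSeq2000 in 9 libraries, 3 for each of 3 groups. Cells were grown in medium (Control), in medium with nanoparticles of molybdenum disulfide (MoS2), or with the nanoparticles and near-infrared light (MoS2_NIR). Groups and replicate numbers were taken from the sample titles. The organism field of the labels names the rat, while the source, the cell line, the genome build mm10 and the mouse Ensembl identifiers in the table all name the mouse. The values were therefore treated as mouse genes. Per the submitters' processing notes, Bowtie 0.12.9, Cufflinks 2.1.1, HTSeq (no version) and mm10 were used, and the notes do not say for which step. The strand setting of the counting is not stated, so a gene and an antisense partner cannot be separated. The available gene annotation is a rat assembly, so it was not used, and gene symbols and identifiers are those of the deposited table. Positions of genes on mm10 were not analysed here.

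The deposited table holds 2392 genes with 1 score per library. Each gene's scores were standardized by the authors over the 9 libraries: in 2391 genes they have a mean of 0 and a population standard deviation of 1, and in 1 gene (Gm10736) every score is 0. How the authors selected these genes is not stated. Libraries were not pooled, and no other file was analysed here.

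Because such scores hide the level and the size of a change, the values behind them were recovered. For each gene a search was made for 9 values with a step of 0.01 whose natural logarithm, after adding 1, gives the deposited scores when standardized, within a score tolerance of 3e-09. A solution was accepted only where the expected number of solutions by chance was below 0.001, and the largest among accepted genes was 4.9e-05. Values were recovered for 2390 genes (99.92%), and the largest score difference after standardizing them again was 5e-10. Gm10736 and Nop56 gave no solution. For 9 genes, of which none is named in the results, the level is known only up to a whole-number factor. In a test on simulated scores 400 of 400 genes were returned with the right values, and 0 of 60 genes with random scores were accepted. The random scores held no ties and were searched over a narrower range of levels than the table, so that check was milder. The limits of the search were tightened after a looser search had returned spurious solutions. Of 148 genes with at least 3 libraries tied at the lowest score, 133 had a lowest value of 0 with no lower limit set. The unit of the recovered values is not stated. They carry 2 decimals and are not whole counts, and no common step that 1 read would give was found: over 36 pairs of libraries at most 13.3% of the ratios of genes with low values fell within 2% of a single value. The depth of the libraries is therefore unknown, and no counting interval or limit of detection is given. The plan written before the data were examined had expected counts or a named unit such as FPKM, and its test for normalized values was used.

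The 1747 genes with a value of at least 1 in at least 3 of the 9 libraries were tested, and 643 were below that limit. The values were not scaled again between libraries. A pseudocount of 1 was added and log2 values were fitted with limma 3.58.1 in R 4.3.3, with an intensity trend and robust variance moderation. All 9 libraries entered 1 fit with 6 residual degrees of freedom. Adjusted p-values from limma are Benjamini-Hochberg values over the 1747 genes of a comparison, and a gene was called higher or lower at an adjusted p under 0.05. Log2 fold changes are differences of group means of log2 (value + 1), and means, standard deviations (SD) and ratios are on the scale of the recovered values. On simulated data with 200 of 1747 genes changed, limma called 48 of 100 genes with a log2 change of 0.5 and 91 of 100 with a change of 1 for MoS2 against Control. It called 51 and 93 of 100 for MoS2_NIR against Control, and 51 and 84 of 100 for MoS2_NIR against MoS2. Every called changed gene had the right sign, and unchanged genes made up 4.1%, 7.1% and 7.5% of the calls. The simulated changes were evenly up and down. In the data far more genes were called, and more of them higher than lower, so these shares do not carry over to the comparisons. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples.

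Before the data were examined, 27 gene lists were written, along with the comparisons, the tests, most alternatives and a rule for the genes to name. The lists cover heat shock and chaperones, endoplasmic reticulum chaperones, the ATF4 response, NRF2 and antioxidant enzymes, the metal response, immediate early genes, p53 targets, apoptosis, necroptosis and pyroptosis, and ferroptosis. They also cover the interferon response, antigen presentation, NF-kB cytokines, glycolysis, hypoxia, oxidative phosphorylation, S phase, mitosis, DNA repair, lysosome and autophagy, epithelial and mesenchymal state, endocytosis, ribosomal proteins, immune cell markers, fibroblast, endothelial and adipocyte markers, and markers of 4T1 cells. The 11 lists with at least 5 tested members were tested in the 3 comparisons with camera from limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 11 lists of each comparison, 33 tests in all. Camera compares the members with the other genes of the table, so its result is relative to the shift of all genes. Some genes stand in more than 1 list. Most listed genes were not in the table of selected genes. It held 6 of 30 heat shock, 15 of 34 interferon, 6 of 19 antigen presentation and 7 of 31 apoptosis genes. Counts of members describe only the genes tested and not a whole pathway. 1 list and some genes that the naming rule took are not reported here.

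Per comparison the naming rule took the 6 genes higher and the 6 lower with the largest log2 fold change among called genes without overlap between the groups' 3 values, with a mean of at least 5 in the higher group and a symbol that is not a predicted gene. It added up to 3 called members with the smallest p of each list that passed its test or had at least 3 called members, and a fixed panel of 8 stress genes. Genes named only to spell out a count of 5 or fewer, and the genes of the overlap between comparisons, were chosen after their values were seen.

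Alternatives were median-ratio scaling and quantile normalization of the values, limma without trend, no filter, a minimum of 5 in 3 libraries, pseudocounts of 0.1 and 5, the replicate number as a block, a fit of only the 2 groups compared, a fold change of at least 2, and each library left out in turn. For lists, camera with an estimated correlation and the fry test of limma were added. After the data were seen, a fit of the deposited scores and an adjustment for 10 times as many genes were added. Recovery and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.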

Results

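Gene expression was measured in 4T1 mouse mammary carcinoma cells kept in medium (Control, n = 3), given molybdenum disulfide nanoparticles (MoS2, n = 3), or given the nanoparticles and near-infrared light (MoS2_NIR, n = 3). Molybdenum disulfide absorbs near-infrared light and releases it as heat, and the title of the series concerns photothermal therapy of tumours at low temperature. No group received light without particles, so the effect of light was measured only in cells with particles. The deposited table holds 2392 genes, and expression values were recovered for 2390 of them. Their median per library was 1.98, 1.91 and 1.63 in Control, 2.07, 1.96 and 2.0 in MoS2, and 3.26, 3.19 and 3.25 in MoS2_NIR. The unit of the values is not stated and the depth of the libraries is unknown. The table is a selection of genes: in 2095 of them the largest ratio between group means was at least 2, and in 32 it was below 1.5. Counts of calls and p-values therefore describe genes already picked, by a rule that is not stated, and are not independent evidence of how much of the transcriptome moved. Libraries of 1 group had Pearson correlations across genes of 0.975 to 0.984.

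The comparison of MoS2 with Control asks what the particles do without light. The highest log2 fold change among called genes with a mean of at least 5, predicted genes aside, was that of Il31ra (ENSMUSG00000050377), the receptor of interleukin-31, which went from 421 ± 176 to 1422 ± 368 (SD, n = 3 each; log2 fold change 1.81, SE 0.34, limma adjusted p = 0.00518). Fosl1 (ENSMUSG00000024912), which encodes the AP-1 subunit FRA-1, rose from 11.7 ± 2.18 to 34.5 ± 4.54 (log2 fold change 1.48, SE 0.15, limma adjusted p = 0.00019). Tuba1c (ENSMUSG00000043091) and Tubb4b, genes of alpha- and beta-tubulin, rose from 59.7 ± 0.816 to 153 ± 6.69 and from 104 ± 5.80 to 231 ± 9.47 (limma adjusted p = 8.67e-06 and 3.09e-05). Among the genes with the largest decreases were Mmp9 (ENSMUSG00000017737), a secreted matrix protease, which fell from 47.8 ± 8.11 to 20.7 ± 1.26 (log2 fold change -1.16, limma adjusted p = 0.00019), and Zbp1 (ENSMUSG00000027514), a sensor of Z-form nucleic acids that can start necroptosis, which fell from 12.2 ± 0.487 to 4.82 ± 0.884 (log2 fold change -1.19, limma adjusted p = 0.000745). Cbr2 fell from 54.1 ± 2.07 to 24.1 ± 1.38 and Tpm2 from 10.1 ± 1.19 to 4.07 ± 1.04 (limma adjusted p = 3.39e-05 and 0.00083). Reads of the tubulin genes may be split between close copies, so their levels are uncertain.

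For 3 further genes among the largest changes after MoS2 the call depended on single libraries. The noncoding RNA Rmrp went from 1.47 ± 0.742 to 6.06 ± 1.25 (limma adjusted p = 0.0477), and its call ended without any 1 of the 6 Control and MoS2 libraries or without MoS2_NIR replicate 3, with the highest limma adjusted p among these of 0.119 without MoS2 replicate 1. The call also ended with a pseudocount of 5 (log2 fold change 0.77 in place of 1.54, limma adjusted p = 0.154), after median-ratio scaling (0.0632) and after quantile normalization (0.0567). Cox7a1 went from 6.93 ± 0.445 to 2.19 ± 0.679 (limma adjusted p = 0.0166, and 0.0566 without MoS2 replicate 2). Amhr2 went from 44.7 ± 12.5 to 18.6 ± 2.06, with a limma adjusted p of 0.0230 that was 0.0664 without Control replicate 1, 0.0581 without MoS2 replicate 2 and 0.0656 without MoS2 replicate 3.

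Of 6 heat shock and chaperone genes tested, 3 were higher after MoS2 and 0 lower, and 2 were higher under either scaling. Hsph1, a partner of HSP70, rose from 29.4 ± 2.44 to 60.2 ± 3.02 (log2 fold change 1.01, limma adjusted p = 0.00029), and the small heat shock gene Hspb8 rose from 28.5 ± 1.17 to 44.0 ± 1.14 (0.61, limma adjusted p = 0.00058). Cryab went from 10.0 ± 0.708 to 13.9 ± 2.04 (limma adjusted p = 0.0168), a call that ended after median-ratio scaling (log2 fold change 0.12 in place of 0.43, limma adjusted p = 0.489), after quantile normalization (0.0537), and without Control replicate 1 (0.0577) or MoS2 replicate 3 (0.0665). The HSP70 gene Hspa1b was 40.4 ± 6.84 in Control and 59.2 ± 2.78 in MoS2 (log2 fold change 0.55, SE 0.51, limma adjusted p = 0.389), and its near-identical copy Hspa1a was 0.0567 ± 0.0306 and 0.183 ± 0.0902 (0.16, limma adjusted p = 0.809). The shared fit gives Hspa1b the wide spread of the MoS2_NIR libraries; with only MoS2 and Control fitted its limma adjusted p was 0.0133. Hspb1 was listed at 0 in all 6 of these libraries. The remaining panel genes, Hsp90aa1, Dnajb1, Hmox1, Ddit3, Mt1 and Cdkn1a, were not among the genes analysed here. Against the other genes of the table the list did not pass (camera adjusted p = 0.213).

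Some members of the ATF4 and NRF2 lists were higher after MoS2. Sesn2, a target of ATF4, rose from 2.69 ± 0.121 to 4.52 ± 0.432 and Atf3 from 5.33 ± 0.622 to 9.92 ± 0.834 (limma adjusted p = 0.00226 and 0.004). Stc2 went from 3.94 ± 0.325 to 5.81 ± 0.51 (limma adjusted p = 0.0489), and its call ended without any 1 of the 6 Control and MoS2 libraries or MoS2_NIR replicate 2, with 0.129 without MoS2 replicate 1 as the highest limma adjusted p among these. Its call also ended after median-ratio scaling (log2 fold change 0.20 in place of 0.46, limma adjusted p = 0.353), after quantile normalization (0.218), with a pseudocount of 5 (0.102), without trend (0.0517) and without a filter (0.0587). Txnrd1, the thioredoxin reductase under control of NRF2, rose from 39.8 ± 7.23 to 76.9 ± 5.38 (log2 fold change 0.95, limma adjusted p = 0.000576), with Osgin1 at 0.62 and Srxn1 at 0.57 on the log2 scale, while Gstm1 and Sod3 of the same list fell. The ATF4 list had 3 of 6 members higher and 0 lower (camera adjusted p = 0.282), or 2 higher and 2 lower after median-ratio scaling. The NRF2 list had 3 higher and 2 lower of 5 (camera adjusted p = 0.604). Among 13 immediate early genes, which answer signals without new protein, 8 were higher, among them Fosl1, Dusp4 (17.0 ± 2.39 to 28.1 ± 1.15) and Atf3, and only Myc was lower (camera adjusted p = 0.168, and 0.0337 without a filter). After median-ratio scaling 4 were higher and 3 lower, and after quantile normalization 7 were higher and 0 lower, since the call of Myc ended (limma adjusted p = 0.0446, then 0.141). Of 10 NF-kB cytokine genes 4 were higher and 1, Ccl5, lower (camera adjusted p = 0.282; 4 and 3 after median-ratio scaling). The neutrophil chemokines Cxcl5 and Cxcl1 rose from 54.9 ± 3.71 to 106 ± 1.56 and from 109 ± 5.79 to 204 ± 9.61, and the growth factor gene Csf3 rose from 63.0 ± 0.878 to 118 ± 4.75 (limma adjusted p = 0.000253, 0.000524 and 0.000666).

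Most interferon and antigen presentation genes tested were called lower after MoS2. Of 13 interferon response genes 9 were lower and 1, Cgas, higher (9 became 10 when adjusted over the list alone). Ifi27 fell from 129 ± 8.10 to 85.3 ± 4.29, Oasl2 from 19.1 ± 1.26 to 12.3 ± 0.325 and Oas1a from 13.5 ± 0.321 to 9.14 ± 0.522 (limma adjusted p = 0.00136, 0.00196 and 0.00247). The list passed (camera adjusted p = 0.000323), but not with an estimated correlation (camera adjusted p = 0.12 with an estimated correlation). Of 6 antigen presentation genes 4 were lower, and 6 were lower when adjusted over the list alone. The immunoproteasome genes Psmb8 and Psmb9 fell from 27.9 ± 0.977 to 17.0 ± 2.21 and from 5.83 ± 0.715 to 3.37 ± 0.135, and B2m, the light chain of MHC class I, fell from 1229 ± 72.4 to 1015 ± 49.6 (limma adjusted p = 0.0014, 0.00237 and 0.00961). After quantile normalization the limma adjusted p of B2m was 0.300. The antigen list passed (camera adjusted p = 0.00352; camera adjusted p = 0.193 with an estimated correlation). Both lists had 0 or 1 member higher under every scaling.

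In the epithelial and mesenchymal list, Mmp9 and Fn1, the fibronectin gene (433 ± 81.4 to 263 ± 13.0, limma adjusted p = 0.00277), were the 2 genes lower of 6 (camera adjusted p = 0.0238; camera adjusted p = 0.452 with an estimated correlation, 0.0912 after quantile normalization). Among 5 markers of 4T1 cells, the lipocalin gene Lcn2 fell from 399 ± 20.2 to 233 ± 8.05 and the osteopontin gene Spp1 from 1242 ± 43.4 to 962 ± 30.1 (limma adjusted p = 0.000199 and 0.00217), Csf3 rose, and the list did not pass (camera adjusted p = 0.373). Of 7 apoptosis genes 3 were lower (2 when adjusted over the list alone; camera adjusted p = 0.125, and 0.0231 after median-ratio scaling). Bcl2l11, which encodes the cell death protein BIM, fell from 31.5 ± 3.58 to 22.6 ± 1.30 (limma adjusted p = 0.00694). Fas went from 27.0 to 20.7 (limma adjusted p = 0.0313), and its call ended without Control replicate 1 or 2 or any 1 MoS2 library (highest limma adjusted p of 0.103, without MoS2 replicate 1). Casp12 went from 6.16 to 4.31 (limma adjusted p = 0.0496), and its call ended without Control replicates 1 or 3, any 1 MoS2 library or MoS2_NIR replicate 2 (highest limma adjusted p of 0.143, without Control replicate 1), as well as with a pseudocount of 0.1 (0.0792) and without a filter (0.0588). Of 6 p53 targets Aen rose from 4.17 ± 0.0569 to 7.41 ± 0.317, while Gadd45a fell from 116 ± 13.3 to 82.8 ± 6.93 (limma adjusted p = 0.00058 and 0.00597), and Fas and Plk2 were lower (camera adjusted p = 0.5, with the median at -0.10, the mean at -0.01 and fry in the upward direction). For the other lists the counts were the same when adjusted over the list alone.

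Lists with fewer than 5 tested members were only counted, and their members are named here after their values were seen. After MoS2, Slc30a1 and Suox of the 3 tested members of the metal response list were higher (0 after median-ratio scaling), as were Egln3 of 3 hypoxia genes (1 higher and 2 lower after median-ratio scaling), the mitochondrial transcripts mt-Nd1 (478 ± 23.7 to 835 ± 50.9) and mt-Nd2 of oxidative phosphorylation, and Exo1 and H2ax of DNA repair. Pfkfb3 (glycolysis), Map1lc3b (autophagy, 144 ± 2.44 to 90.8 ± 5.49), Postn (fibroblast marker) and Zbp1 (necroptosis) were lower, and Gch1 (ferroptosis), Ccne1 and Ccne2 (S phase) were not called (1 of these lower after median-ratio scaling). The lists for endoplasmic reticulum chaperones, mitosis, endocytosis, ribosomal proteins and immune cell markers had 0 genes in the table.

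Of the 1747 tested genes limma called 525 higher and 294 lower after MoS2, and 928 were not called. The fold change reached 2 for 20 of the higher and 26 of the lower genes. In 57.4% of the tested genes the 3 MoS2 values did not overlap the 3 Control values. Chance gives 10% for genes not picked by their values, which is no baseline for a selected table. The median log2 fold change of all tested genes was 0.17, and it was -0.04 after median-ratio scaling and 0.08 after quantile normalization. The split changed with it, to 230 higher and 542 lower after median-ratio scaling and 405 higher and 362 lower after quantile normalization. Median-ratio scaling assumes that most genes of the table did not change. Quantile normalization assumes the same distribution of values in every library. A table of selected genes makes both assumptions doubtful.

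The comparison of MoS2_NIR with Control measures the whole treatment. Hspa1b (ENSMUSG00000090877), the inducible HSP70 gene that cells switch on when proteins unfold in heat, had the highest log2 fold change of the genes open to naming. It was 40.4 ± 6.84 in Control and 588 ± 405 after light (SD, n = 3 each; log2 fold change 3.57, SE 0.51, limma adjusted p = 0.000274), with 206, 1014 and 544 in the 3 irradiated libraries. Hspa1a went from 0.0567 ± 0.0306 to 10.8 ± 8.52 (log2 fold change 3.17, limma adjusted p = 0.000516), and reads of these near-identical copies may be split between them. As a ratio of group means the increase of Hspa1a was larger (191 against 14.5 for Hspa1b), from a Control value near 0. Hspb1, the gene of HSP27, was listed at 0 in Control and at 3.09, 12.5 and 5.42 after light. Without MoS2_NIR replicate 2 the means after light were 375 for Hspa1b, 6.43 for Hspa1a and 4.26 for Hspb1. Cryab rose to 29.7 ± 3.13, Hspb8 to 69.9 ± 0.803 and Hsph1 to 71.2 ± 10.7 (limma adjusted p = 9.09e-07, 2.19e-07 and 2.12e-06). All 6 tested genes of the 30 listed were higher after light, 4 of them after median-ratio scaling, where Hspb8 and Hsph1 were no longer called (limma adjusted p = 0.0941 and 0.416). The list did not pass against the other genes (camera adjusted p = 0.121), but did without MoS2_NIR replicate 1 (0.0363) and after quantile normalization (0.0416).

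**Figure D1:**
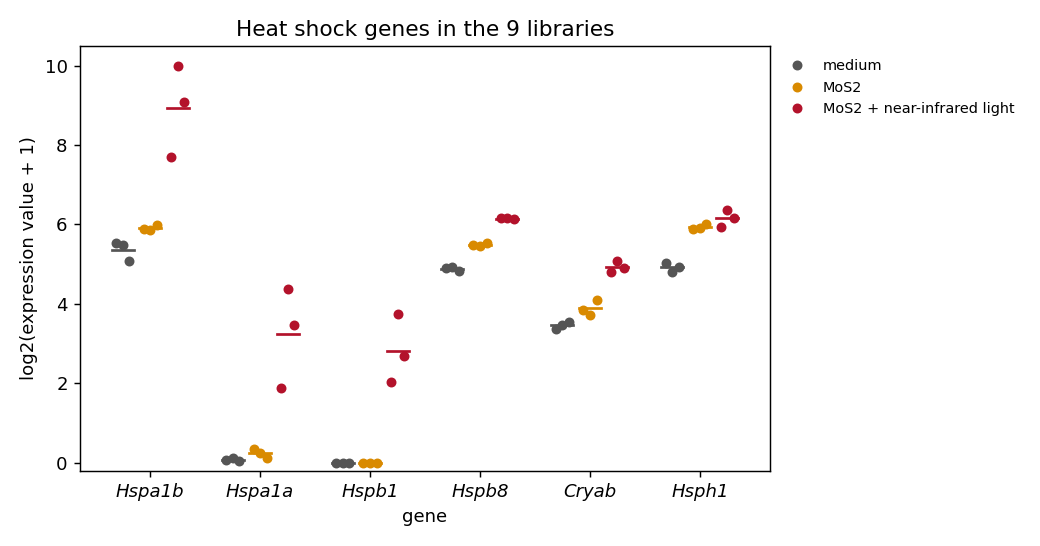
Log2 (expression value + 1), in the unstated unit of the submitters, for the 6 tested heat shock genes, with 1 point per library (9 libraries, coloured by group) and a bar at the mean of each group. The expression value of Hspa1b lies at 32.6 to 62.4 in the 6 libraries without light and at 206 to 1014 with light, and under median-ratio scaling Hspb8 and Hsph1 were not called higher than in Control.

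Fosl1 went up about as far as Hspa1b and with less spread, from 11.7 ± 2.18 to 137 ± 18.3 (log2 fold change 3.44, SE 0.15, limma adjusted p = 5.32e-08). Tuba1c rose from 59.7 ± 0.816 to 466 ± 31.4, Ppan, a ribosome assembly gene, from 11.2 ± 1.89 to 85.4 ± 6.12, and the host transcript of microRNA 22, Mir22hg, from 2.11 ± 1.40 to 23 ± 2.29 (limma adjusted p = 2.14e-09, 5.48e-08 and 6.03e-06; the Control mean of Mir22hg was 1.34 without replicate 2). Among the largest decreases was Zfp986, a zinc finger gene with close copies, from 91.6 ± 31.4 to 6.57 ± 7.87 (log2 fold change -4.05, SE 0.68, limma adjusted p = 0.000723), with a mean of 2.03 without MoS2_NIR replicate 3. The histone genes H1f2 and H2aw fell from 45.1 ± 1.27 to 4.45 ± 1.34 and from 25.3 ± 1.32 to 3.18 ± 0.871 (limma adjusted p = 8.84e-08 and 9.01e-08), and histone genes have near-identical copies too. Nr1d1, the clock repressor REV-ERB alpha, fell from 285 ± 48.9 to 51.2 ± 10.1, Mmp9 to 8.41 ± 0.625 and Zbp1 to 1.5 ± 0.566 (limma adjusted p = 2.28e-07, 8.84e-08 and 3.25e-07).

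Members of the ATF4 and NRF2 lists went both ways after light. Sesn2 reached 16.4 ± 1.01 (log2 fold change against Control 2.24, limma adjusted p = 6.03e-08) and Trib3, a pseudokinase induced by ATF4, rose from 18.1 ± 1.61 to 63.8 ± 6.27 (1.76, limma adjusted p = 1.36e-07), while Ddit4 fell from 308 ± 34.2 to 149 ± 7.87 (-1.04, limma adjusted p = 1.81e-06). With Ddit4 and Aldh1l2 lower, the ATF4 list had 4 higher and 2 lower of 6 (camera adjusted p = 0.791). Txnrd1 reached 154 ± 0.589, Osgin1 39.0 ± 0.816 and Srxn1 48.4 ± 0.825 (limma adjusted p = 2.2e-07, 2.04e-07 and 3e-07), and Gstm1 and Sod3 were lower (camera adjusted p = 0.945). The metal response list had 3 of its 18 genes tested. Its members Suox and Slc30a1, a zinc exporter, rose from 2.03 ± 0.182 to 6.67 ± 0.456 and from 0.753 ± 0.0513 to 3.36 ± 0.401 (limma adjusted p = 8.43e-07 and 1.04e-06). The metal sensor gene Mtf1 rose from 6.24 ± 1.34 to 13.0 ± 0.767 (limma adjusted p = 0.000165), except that after median-ratio scaling its log2 fold change was -0.061 (limma adjusted p = 0.703) and after quantile normalization its limma adjusted p was 0.0993. Of 13 immediate early genes 9 were higher, among them Fosl1 and Ier3 (188 ± 11.1 to 532 ± 49.9), and Fos, Klf10 and Gadd45b (258 ± 16.9 to 84.3 ± 9.56) were lower (camera adjusted p = 0.579). Of 10 NF-kB cytokine genes 6 were higher, with Cxcl5 at 233 ± 34.1 and Cxcl1 at 385 ± 67.6, and 4 lower: Ccl5, Csf1, Il11 and the NF-kB inhibitor Nfkbia (247 ± 7.92 to 128 ± 1.73). Their median log2 fold change was 1.44 and their mean 0.67, but camera put the list below the other genes (camera adjusted p = 0.941).

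Most interferon and all antigen presentation genes tested were lower than in Control after light. Irf1 (ENSMUSG00000018899), a transcription factor that drives interferon-stimulated and MHC class I genes, fell from 227 ± 14.5 to 59.6 ± 2.15 (log2 fold change -1.91, limma adjusted p = 4.19e-08). Oas1a fell to 6.39 ± 0.369 and the tethering factor gene Bst2 from 201 ± 5.95 to 118 ± 5.62 (limma adjusted p = 2.65e-06 and 3.5e-06). Of 13 interferon response genes 11 were lower, and Cgas, the DNA sensor, was the 1 higher, from 1.25 ± 0.246 to 4.60 ± 0.533. The list passed (camera adjusted p = 0.000257; camera adjusted p = 0.114 with an estimated correlation). B2m fell to 653 ± 23.3, Psmb8 to 9.36 ± 0.853 and Psmb9 to 1.54 ± 0.163 (limma adjusted p = 5.52e-07, 5.57e-07 and 8.34e-07), and all 6 antigen presentation genes were lower, also under both scalings (camera adjusted p = 0.00139; camera adjusted p = 0.159 with an estimated correlation). Reads of Oas1a and Oasl2 may be shared with their close copies.

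**Figure D2:**
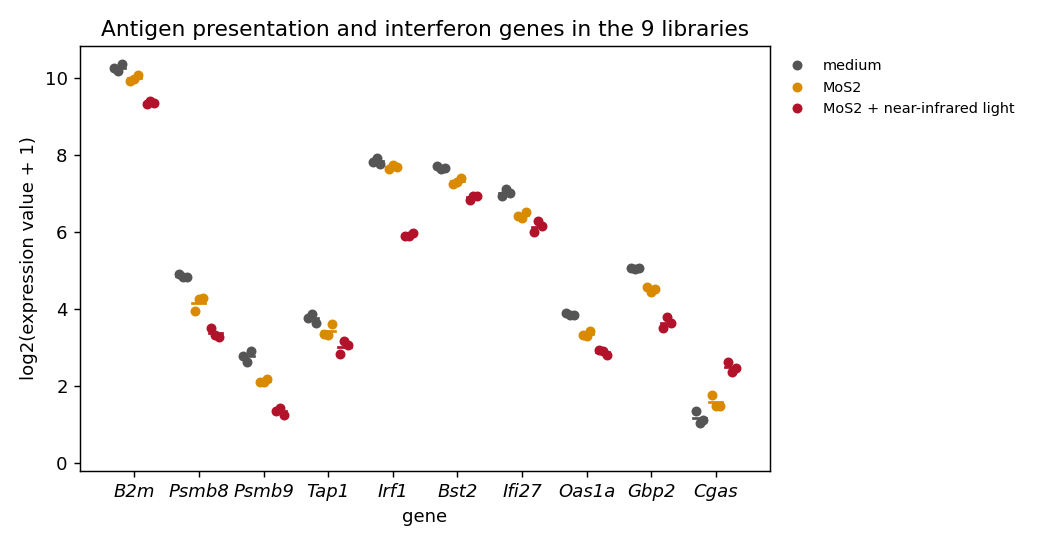
Log2 (expression value + 1), in the unstated unit of the submitters, for 10 interferon and antigen presentation genes, with 1 point per library (9 libraries, coloured by group) and a bar at the mean of each group. The mean expression value of B2m goes from 1229 in Control to 1015 in MoS2 and 653 in MoS2_NIR, and Cgas is the gene that is higher after light, at 1.25 in Control and 4.6 in MoS2_NIR, also under both scalings.

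The apoptosis list passed in the downward direction (6 lower and 1 higher of 7, camera adjusted p = 0.0147; camera adjusted p = 0.282 with an estimated correlation). Fas, a death receptor gene, fell to 8.88 (log2 fold change -1.52, limma adjusted p = 7.75e-07), Bcl2l11 to 17.4 ± 1.08 and Casp12 to 2.14, and the inhibitor gene Cflar was the 1 higher (18.6 ± 0.146 to 27.9 ± 1.53). Birc2, an inhibitor gene too, was among the 6 lower (15.7 ± 1.83 to 11.8 ± 1.28, limma adjusted p = 0.0105). It is named here after its values were seen. Under both scalings 0 of the 7 were higher, and after median-ratio scaling all 7, Cflar included, were called lower. Of 6 p53 targets Aen, Zmat3 and Plk2 were higher, Aen at 15.7 ± 0.801 and Plk2 at 112 ± 3.57 (limma adjusted p = 1.05e-07 and 5.57e-07), and Fas, Bbc3 and Gadd45a were lower. Plk2 was not called after median-ratio scaling (limma adjusted p = 0.0766). The p53 median was 0.21 and the mean 0.13, while camera put the list below the other genes (camera adjusted p = 0.687), and the median turned negative under both scalings. All 6 genes of the epithelial and mesenchymal list were lower, also under both scalings, with Fn1 at 185 ± 20.5 (camera adjusted p = 0.00139; camera adjusted p = 0.159 with an estimated correlation). Among 4T1 markers Lcn2 fell to 98.9 ± 8.79, Spp1 to 560 ± 28.4 and Csf1 from 122 ± 15.9 to 49.8 ± 2.51 (limma adjusted p = 4.19e-08, 1.22e-07 and 7.83e-07), Ly6e was lower and Csf3 higher (0 higher after median-ratio scaling). That list passed with camera adjusted p = 0.0362, against 0.159 with an estimated correlation, 0.0517 without MoS2_NIR replicate 3, 0.0619 after median-ratio scaling and 0.101 after quantile normalization.

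In the smaller lists, the hypoxia gene Egln3 rose from 46.2 ± 4.36 to 164 ± 17.5 while Adm (75.1 ± 6.40 to 36.4 ± 2.49) and Ddit4 fell. Transcripts of mt-Nd1 reached 1776 ± 104 and of mt-Nd2 1203 ± 107, and Exo1 and H2ax were higher under every scaling. Ccne1 and Ccne2 of S phase were higher (2.08 ± 0.297 to 5.66 ± 1.38 and 4.13 ± 0.78 to 8.65 ± 0.789), but 0 of them after median-ratio scaling and 1 after quantile normalization. Gch1 of ferroptosis was higher (4.47 ± 0.389 to 7.75 ± 1.44, limma adjusted p = 0.00231) and not called under either scaling. Pfkfb3, Map1lc3b, Postn and Zbp1 were lower under every scaling. Counts adjusted over the list alone equalled those over all genes tested for every list in this comparison and in the next.

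Limma called 1109 of the 1747 tested genes higher and 592 lower in MoS2_NIR than in Control, 878 and 244 of them by at least 2-fold, and 46 were not called. The values of both groups did not overlap in 96.4% of the genes, where chance gives 10% for genes not picked by their values. The median log2 fold change of all tested genes was 1.01, and it was 0.16 after median-ratio scaling and 0.44 after quantile normalization. The split became 607 higher and 634 lower after median-ratio scaling, and 985 and 613 after quantile normalization. Some increases, such as those of Cflar and Gch1, were not called as increases under either scaling and therefore rest on the scale of the authors' values.

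The comparison of MoS2_NIR with MoS2 measures the addition of light to cells with particles. Hspa1b rose from 59.2 ± 2.78 to 588 ± 405 and Hspa1a from 0.183 ± 0.0902 to 10.8 ± 8.52 (SD, n = 3; log2 fold change 3.01 and 3.0, limma adjusted p = 0.00101 and 0.001), with means of 375 and 6.43 without MoS2_NIR replicate 2. Hspb1 was listed at 0 in MoS2 and had a mean of 7.01 after light (limma adjusted p = 9.09e-05; 4.26 without replicate 2). Cryab and Hspb8 rose by 1.05 and 0.65 on the log2 scale (limma adjusted p = 2.51e-05 and 3.52e-05), while Hsph1 did not pass (0.23, limma adjusted p = 0.0880). After median-ratio scaling Cryab was not called (limma adjusted p = 0.109) and Hspb8 was at -0.14 (limma adjusted p = 0.116). With 5 of 6 genes higher (3 higher and 1 lower after median-ratio scaling) the heat shock list did not pass (camera adjusted p = 0.188), but did without MoS2_NIR replicate 1 (0.0376) and after quantile normalization (0.0344).

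Mir22hg rose from 2.23 ± 0.806 to 23 ± 2.29, Tlcd2 from 2.33 ± 0.229 to 16.4 ± 1.83 and the lactate transporter gene Slc16a8 from 0.217 ± 0.1 to 5.33 ± 0.361 (limma adjusted p = 2.04e-05, 3.29e-07 and 4.58e-07). Fos, an AP-1 gene like Fosl1, fell from 46.3 ± 4.67 to 8.77 ± 5.73 (log2 fold change -2.44, limma adjusted p = 0.000359; mean 5.62 without MoS2_NIR replicate 3), while Myc rose from 53.1 ± 2.47 to 183 ± 8.82 (1.77, limma adjusted p = 8.37e-07). Zfp986 fell from 101 ± 14.5 to 6.57 ± 7.87 (limma adjusted p = 0.00081; mean 2.03 without replicate 3). H2aw, H1f2 and Nr1d1 fell by 2.61, 2.40 and 1.88 on the log2 scale (limma adjusted p = 6.11e-07, 1.1e-06 and 3.87e-06). The small nuclear RNA 7SK fell from 5.18 ± 3.28 to 0.417 ± 0.376 (limma adjusted p = 0.000442), with a mean of 3.29 without MoS2 replicate 1 and of 0.260 without MoS2_NIR replicate 3.

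Irf1 fell from 204 ± 7.12 to 59.6 ± 2.15 with light (limma adjusted p = 3.29e-07), although it had not passed with particles alone (limma adjusted p = 0.147). The chemokine gene Cxcl10 fell from 8.76 ± 0.927 to 3.84 ± 0.966 and Cgas rose from 2.01 ± 0.341 to 4.60 ± 0.533 (limma adjusted p = 0.000145 and 0.000117; 0.0938 for Cgas after median-ratio scaling). The interferon list had 8 of 13 genes lower and 1 higher (camera adjusted p = 0.001; camera adjusted p = 0.104 with an estimated correlation). All 6 antigen presentation genes were lower, B2m, Psmb8 and Psmb9 among them (camera adjusted p = 0.00112; camera adjusted p = 0.104 with an estimated correlation). In the epithelial and mesenchymal list 5 of 6 were lower, with the transcription factor gene Snai1 going from 120 ± 13.5 to 36.0 ± 8.16 (limma adjusted p = 1.11e-05), and the list passed (camera adjusted p = 0.001; camera adjusted p = 0.134 with an estimated correlation). Mmp9 was among the 5. The apoptosis list had 5 of 7 lower (camera adjusted p = 0.00727; camera adjusted p = 0.243 with an estimated correlation), with Fas and the p53 target Bbc3 (21.2 ± 2.55 to 11.1 ± 1.30) lower and Cflar higher by 0.48 on the log2 scale, but at -0.30 after median-ratio scaling (limma adjusted p = 0.0270). The 4T1 markers Csf1, Lcn2, Spp1 and Ly6e were lower and Csf3 higher (0 higher after median-ratio scaling; camera adjusted p = 0.00727, camera adjusted p = 0.104 with an estimated correlation, 0.0616 after quantile normalization).

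The other lists of at least 5 tested members did not pass in this comparison. Sesn2, Trib3, Atf3 and Stc2 of the ATF4 list were higher and Ddit4 lower (camera adjusted p = 0.823), or 2 higher and 2 lower after median-ratio scaling. Osgin1, Srxn1 and Txnrd1 of the NRF2 list were higher and Gstm1 lower (camera adjusted p = 0.849), and Txnrd1 was not called after median-ratio scaling (limma adjusted p = 0.115). Of 13 immediate early genes 9 were higher, with Myc and Ier3, and Fos, Klf10 and Gadd45b lower (camera adjusted p = 0.772). Of 10 NF-kB cytokine genes 6 were higher, with Csf2 going from 1.71 ± 0.486 to 8.70 ± 1.56, and Csf1 and Nfkbia lower (camera adjusted p = 0.772). The median log2 fold change of this list was 0.64 and its mean 0.32, camera put it below the other genes, and after median-ratio scaling 2 were higher and 4 lower. Of 6 p53 targets Plk2, Aen and Zmat3 were higher and Fas, Bbc3 and Gadd45a lower (camera adjusted p = 0.693, downward, with the median at 0.16 and the mean at 0.14). Aen was not called after median-ratio scaling (limma adjusted p = 0.0504). In the smaller lists Slc30a1, Suox, Mtf1, Egln3, mt-Nd1, mt-Nd2, Ccne1, Ccne2, Exo1 and H2ax were higher, Ddit4, Adm, Pfkfb3, Map1lc3b, Postn and Zbp1 were lower and Gch1 was not called. After median-ratio scaling Mtf1, both mitochondrial genes, both DNA repair genes and 1 of the S phase genes were no longer called.

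Limma called 1077 genes higher and 444 lower in MoS2_NIR than in MoS2, 407 and 81 of them by at least 2-fold, and 226 of the 1747 were not called. Values of both groups did not overlap in 87.4% of the genes, where chance gives 10% for genes not picked by their values. The median log2 fold change of all tested genes was 0.68, and it was 0.03 after median-ratio scaling and 0.22 after quantile normalization. The split became 415 higher and 611 lower after median-ratio scaling and 686 and 542 after quantile normalization.

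The changes of MoS2 and of MoS2_NIR against Control mostly went the same way. Limma called 808 genes in the same direction in both comparisons, 522 higher and 286 lower, where independent lists of these sizes would share 333 and 99.6. Log2 fold changes correlated across genes with r = 0.82, and simulated unchanged groups with shared simulated controls gave 0.50 (100 simulations). The simulated genes were not selected, while the table is a selection, so simulated values here hold only for unselected genes without change. Genes are not independent replicates. The covariance was 0.471 against a simulated 0.0214, a difference of 0.450, and 91.5% of genes had the same sign against a simulated 66.6%. In 20 simulations of calls 0 genes were called in both comparisons. Groups simulated without change give few calls at all, so this 0 says little about the 808 shared calls. With 3 Control libraries the controls could not be split into parts of at least 2, so part of the excess of shared calls over independent lists may come from the shared controls. With no Control library in common the covariance was still 0.441 to 0.463 in 6 arrangements. The MoS2 mean lay between the Control and MoS2_NIR means for 1017 (91.7%) of the genes called higher and 537 (90.7%) of those called lower after light. These genes were selected by their call after light, and no share without an effect was computed for them. Called in opposite directions were 7 genes, named after their values were seen. Fos (20.8 ± 2.35, 46.3 ± 4.67 and 8.77 ± 5.73 in Control, MoS2 and MoS2_NIR, the last 5.62 without replicate 3), Klf10 (94.9, 124 and 61.9) and Gm50143 (1.17, 2.06 and 0.360) were higher with particles alone and lower with light. Myc (65.5, 53.1 and 183), Plk2 (45.4, 36.8 and 112), Snhg16 (12.1, 8.51 and 24.9) and Nr6a1 (5.12, 3.57 and 6.36) went down with particles alone and up with light. None of the 7 kept opposite calls under both scalings. Only Myc did after median-ratio scaling, and all but Myc and Nr6a1 did after quantile normalization. Nr6a1 was called lower in both comparisons under either scaling. With particles alone the values of Myc in Control and MoS2 overlapped (limma adjusted p = 0.0446, and 0.141 after quantile normalization).

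**Figure D3:**
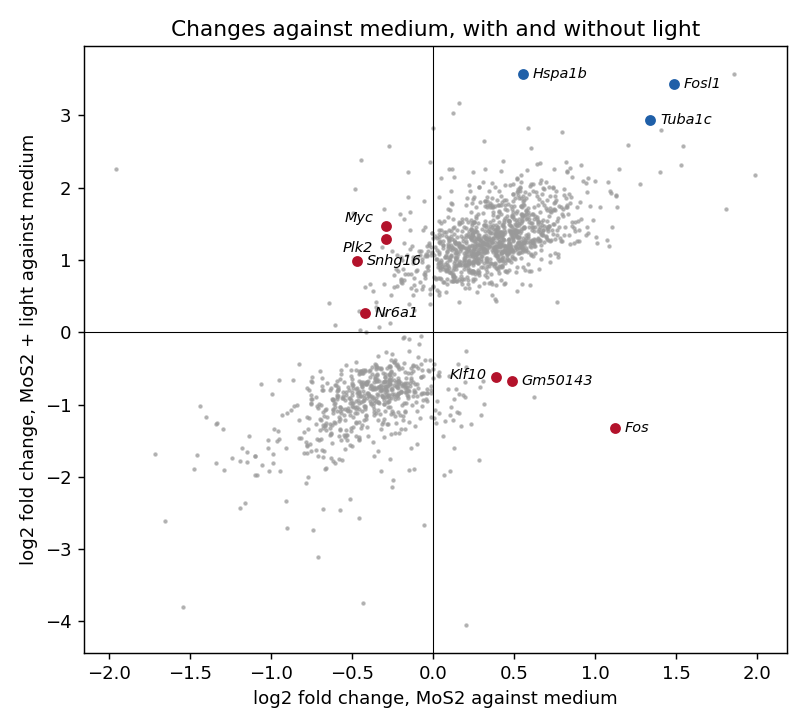
Log2 fold change of MoS2_NIR against Control plotted against that of MoS2 against Control for the 1747 tested genes, 1 point each. Most points, 91.5%, lie where both changes have the same sign, and the 7 genes called in opposite directions, such as Myc and Fos, are drawn in red, with Hspa1b, Fosl1 and Tuba1c in blue.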

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

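The fit of the deposited scores and the adjustment for 10 times as many genes were chosen after the data were seen. Alternatives based on counts were not run because the table holds no counts. Single genes were rerun for the 135 results that the naming rule chose, under every alternative except the fold change of at least 2; other genes named in the text were not. Of these 135 results 133 were called, and 112 kept their direction and side of the threshold under every alternative run for them. Of the 2691 alternative values for these genes, 2613 kept both, 74 lost the call, 1 gained it and 3 reversed. Calls were lost for 11 results in MoS2 against Control, 4 in MoS2_NIR against Control and 7 in MoS2_NIR against MoS2.

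Median-ratio scaling called 230 genes higher and 542 lower in MoS2 against Control, 607 higher in MoS2_NIR against Control and 415 higher in MoS2_NIR against MoS2, and quantile normalization called 686 higher in the last. After median-ratio scaling the 3 that reversed were Mtf1 in MoS2_NIR against Control (log2 fold change -0.061), and Hspb8 (-0.14) and Cflar (-0.30) in MoS2_NIR against MoS2. Outside the 135, Nr6a1 (-0.70), Snhg16 (-0.095), Gch1 (-0.31) and Cflar also turned negative in MoS2_NIR against Control, and others were not searched for. For these changes with scaling the cause was not tested.

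A minimum of 5 in 3 libraries left 1053 genes and so fewer calls, with 684 higher and 348 lower in MoS2_NIR against Control and 665 and 291 in MoS2_NIR against MoS2. A fold change of at least 2 left 20 higher and 26 lower in MoS2 against Control, 244 lower in MoS2_NIR against Control, 407 and 81 in MoS2_NIR against MoS2, and 43 genes called the same way in both comparisons with Control. Adjusted as for 10 times as many genes, 177 were higher and 97 lower in MoS2 against Control, 278 lower in MoS2_NIR against MoS2, and 273 shared. Of the 135 results 11 lost their calls with that adjustment. Among them were Il31ra, Gadd45a, Bcl2l11 and B2m in MoS2 against Control (limma adjusted p = 0.0518, 0.0597, 0.0694 and 0.0961).

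Of the 33 list tests 13 passed. With an estimated correlation 0 passed (camera), with fry 31, and with the minimum of 5, which allowed 21 tests, 8. Fry, which does not compare a list with other genes, reversed p53 targets and NF-kB cytokines in MoS2_NIR against Control (2.61 and 3.44 as signed -log10 p, upward) and p53 targets in MoS2_NIR against MoS2 (2.43).

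The same replicate number did not pair libraries: correlations of deviations between same-numbered libraries ran from -0.0805 to 0.0996. With the replicate number as a block, 503 genes were higher and 272 lower in MoS2 against Control, 1110 and 596 in MoS2_NIR against Control and 1073 and 442 in MoS2_NIR against MoS2. Of the 135 results Rmrp and Casp12 in MoS2 against Control lost their calls.

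Leaving out 1 of the 9 libraries gave 405 to 517 higher and 212 to 322 lower in MoS2 against Control, 1096 to 1110 and 571 to 593 in MoS2_NIR against Control, 1050 to 1082 and 400 to 446 in MoS2_NIR against MoS2, 634 to 786 shared genes and 12 to 15 list tests passed. The depth of the libraries is unknown, so its effect was not tested.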

Other observations

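All tests in this part were chosen after the result was seen, except the test of a weaker response of the whole culture. Both scalings were planned as alternatives, but their use as tests in this part was not. The gene groups in the next paragraph were picked after the values were seen, while reading through the gene symbols of the table. Their p-values do not cover that choice. Fisher's exact test was run only on values without rescaling and counts genes as independent, which genes of a group are not. The p-values therefore only describe these groups and are no support for them.

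After light, all 10 tested replication-dependent histone genes were lower than in Control, also under both scalings (Fisher's exact test of higher against lower calls, adjusted over 21 tests, p = 0.000174). Among them H2bc8 went from 15.2 ± 3.42 in Control to 7.63 ± 1.71 in MoS2 and 2.29 ± 1.0 in MoS2_NIR (SD, n = 3). H2ax, which stands outside that group, was higher (21.1 to 72.8) and H1f0 lower (1163 to 602). All 7 guanylate-binding protein genes, induced by interferon, were lower after light under every scaling (adjusted p = 0.00181, Fisher's exact test), with Gbp2 going from 32.4 ± 0.406 to 11.5 ± 1.27 and Gbp2b from 17.9 to 6.55. Histone and guanylate-binding protein genes have close copies that can share reads. Whether the selection of messenger RNA for the libraries affects values of histone genes, Rmrp, 7SK and mt-Rnr1 was not tested. All 14 ribosome assembly genes were higher (adjusted p = 0.00903, Fisher's exact test; 11 after median-ratio scaling and 13 after quantile normalization, and 0 lower), with Rrs1 going from 3.68 ± 1.05 to 22.1 ± 0.705 and Grwd1 from 3.65 ± 0.546 to 18.8 ± 2.28. Of 67 zinc finger genes named Zfp 62 were higher and 3 lower after light (adjusted p = 1.16e-07, Fisher's exact test; 32 and 4 after median-ratio scaling). After particles alone 17 were higher and 0 lower, but 1 and 4 after median-ratio scaling. All 4 tubulin genes were higher under every scaling (adjusted p = 0.4, Fisher's exact test). Clock genes divided: Per2 (1.16 to 7.19), Cry1 (3.52 to 12.2) and Cry2 (2.54 to 9.15) were higher, and Nr1d1, Per1 (136 to 47.5), Bhlhe40 (410 to 150) and Nfil3 (34.7 to 15.7) lower, under every scaling (adjusted p = 0.369, Fisher's exact test). Of the mitochondrial RNAs mt-Nd1 and mt-Nd2 were higher and the ribosomal RNA mt-Rnr1 lower (log2 fold change -0.80), also under every scaling (adjusted p = 1, Fisher's exact test).

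Splits of the 6 libraries of a comparison into 3 and 3 number 10, which is too few for a share under 0.05. Every other split mixes both groups on each side, so a difference between them enters the spread. Low counts in the other splits were therefore bound to occur, and they are no support for an effect of treatment. In MoS2 against Control limma called 819 genes in the real split and at most 1 in another, so 1 of the 10 splits gave as many. In MoS2_NIR against Control the real split gave 1701 and the highest other 0, and 1 of 10 gave as many. In MoS2_NIR against MoS2 these were 1521 and 0, again 1 of 10.

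Among the irradiated libraries 5 of the 6 heat shock genes were lowest in MoS2_NIR replicate 1, while Hspb8 was highest there (70.6, with 70.1 and 69.0 in replicates 2 and 3). Cryab was at 26.9 in replicate 1 and 33.0 in replicate 2, and Hsph1 at 60.6 and 82.0. The differences were widest for the other members, where the log2 value in replicate 2 was higher than in replicate 1 by 2.29 for Hspa1b, 2.49 for Hspa1a and 1.72 for Hspb1. A difference in library scale is argued against by the median log2 difference of all tested genes between these libraries, which was -0.0266. A weaker response of the whole culture is argued against as well, provided that Control and the irradiated libraries were on the same scale. Over 1651 genes the median share of the change in replicate 1, relative to the other libraries, was 1.05, against 0.989 and 0.962 for replicates 2 and 3. A difference in scale between Control and all irradiated libraries could itself hold these shares near each other. A candidate explanation is a difference in heat dose or in the time between light and harvest to which these heat shock genes respond more steeply than others, but the labels give neither and it was not tested.

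MoS2 values lay between Control and MoS2_NIR for most genes called after light. If RNA of irradiated cells in the MoS2 libraries were the only cause, every gene would have the same share of the change. Shares from separate libraries would then be unrelated across genes, provided that all libraries were on the same scale. Over 1701 genes the lowest Spearman rho between such shares, across genes, was 0.351 (the others 0.361 and 0.593). A difference in scale between the groups, or such RNA beside a response to the particles, would also relate the shares. The test therefore cannot exclude RNA of irradiated cells. Among genes called higher the median share was 0.193 (quartiles 0.101 and 0.293), but it was 0.0343 for Hspa1b, 0.0117 for Hspa1a and 0 for Hspb1. Hspa1a and Hspb1 were at or near 0 without light. Low shares do not hold for the whole heat shock list. Means of Hsph1, Hspb8 and Cryab were 29.4, 28.5 and 10.0 in Control and 60.2, 44.0 and 13.9 in MoS2. In MoS2_NIR these means were 71.2, 69.9 and 29.7. The shared Control libraries are argued against as the whole cause, since with no Control library in common the covariance of both sets of changes was 0.441 to 0.463 in 6 arrangements. The pattern may reflect a response to the particles that light enlarges, by a share that differs between genes. This remains a hypothesis, because no group had light alone, and handling shared by both particle groups was not tested.

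More genes were called higher than lower after light, and the scale of the authors' values could produce such a split. After median-ratio scaling 48.9% of the calls in MoS2_NIR against Control were higher, and after quantile normalization 61.6%, against 65.2% without rescaling. Among genes changed at least 2-fold without rescaling 78.3% were higher. Median-ratio scaling centres a table of selected genes and so fixes its own outcome, quantile normalization gives every library the same distribution of values, and genes outside the table were not analysed here. An effect of scale and a true majority of increases cannot be told apart for these calls.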
